A study of Mus musculus with 12 samples.

How the data were processed

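Ganglion RNA of 12 libraries (3 WT male, 3 WT female, 1 Q84 male, 5 Q84 female, all at 24 weeks) was prepared with poly(A) selection, per the labels' protocols. The tools kallisto 0.46.2 and STAR 2.7.10b and the build GRCm39 are named, without their roles, per the submitters' processing notes, and the columns of the tables are those that kallisto writes, per the file headers. The release of the transcript set is not given in the sources used here. The deposited tables hold, per the file headers, estimated counts, an effective length and TPM for 116313 transcripts in each library. Estimated counts are the authors' estimates per transcript, not whole numbers and not scaled between libraries, and the deposited TPM values are scaled to length and to a fixed total. Effective lengths were not used in the main test.

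Transcripts were assigned to genes by their Ensembl identifier without its version in GENCODE M21, an annotation of GRCm38. Of the transcripts, 98.3% had a match, and the unmatched ones held 0.751 to 0.804% of counts per library and were left out. Because the build differs from that of the files, gene names and the order of genes on chromosomes were used and no coordinates are given. Estimated counts were summed per gene and rounded to whole numbers. Kallisto divides reads shared by similar transcripts by likelihood, so values of near-identical copies are uncertain, and human ATXN3 reads can only be placed on mouse transcripts.

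Genes were filtered with filterByExpr on the 4 groups of genotype and sex, scaled with TMM and tested with the quasi-likelihood test of edgeR 4.0.16 (robust), with Benjamini-Hochberg adjustment and a threshold of 0.05. The model for Q84 against WT and for male against female held sex and genotype, the female comparison held genotype alone, and the interaction added their product. Gene lists, 33 in all, of sensory neuron types, glia, other tissues and cell stress pathways were tested with camera in limma 3.58.1 on log2 CPM (prior count 2, preset correlation 0.01), beside an estimated correlation and fry. Samples, designs, lists, the rule for named genes and most of the alternatives were fixed before the data were examined. DESeq2 1.42.0, limma-voom, other scaling and filters, length-scaled TPM, a replicate block and each library left out were the alternatives.

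For the comparisons of all 12 and of the female libraries the rule named the 12 largest rises and 12 largest falls among genes that passed, had a mean of 1 CPM or more and lay on one side of the WT mean in every Q84 library. Where fewer passed, genes of smallest p filled up to 6 per direction. The rule further named Atxn3 and the other genes of its list of neighbours, every member of a list that passed and otherwise up to 4 of smallest p, the sex-linked genes Xist, Ddx3y, Eif2s3y, Kdm5d and Uty with the 6 autosomal genes of smallest p for sex, and the 3 higher and 3 lower genes of smallest p for the interaction. It was applied again to the 10 libraries left after the libraries labelled WT female 2 and Q84 female 5 were left out, which was decided after the data were seen, because of their Atxn3 levels. No library was moved to another group. Of the genes that this rule takes from the lists, 1 is not reported here, and others are given only within counts of their list or over all lists. The remaining genes called for sex and for the interaction, Acta1, and the values of Gm44821, Mrgprx3-ps, Mrgprb5, Nps, Mrgprd, Akr1c6 and Alb in single libraries were picked after they were seen.

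Log2 fold changes are from the fitted models, and CPM values are scaled with TMM over the 12 libraries. In counts simulated from these libraries the 12-library test recovered 36.0% of genes changed by 1.5-fold, 84.0% by 2-fold, 100% by 4-fold and 98.0% by 8-fold, with 14 false among 173 calls (18454 genes). The 10-library test recovered 38.0%, 84.0%, 98.0% and 98.0%, with 9 false among 168 calls (18314 genes). In both simulations every Q84-labelled library carried the change, and no library went against its label or shared other structure. The percentages therefore do not give the power in the real libraries, least of all in the 12 as labelled. No 2 libraries of one group agreed within sampling noise: the chi-square per degree of freedom between replicates was 30.9 or more.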

Results

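Poly(A) RNA was sequenced from dorsal root ganglia, the clusters of sensory neuron cell bodies beside the spinal cord, of wild-type (WT) mice and of YAC Q84 mice at 24 weeks of age. YAC Q84 mice carry a yeast artificial chromosome with the human ATXN3 gene, whose expanded CAG repeat causes spinocerebellar ataxia type 3, and the series asks what differs in their peripheral sensory tissue. The 12 libraries were labelled as 3 WT males, 3 WT females, 1 Q84 male and 5 Q84 females. Total estimated counts per library ran from 66490481 to 86891563. The mean was 77780340 ± 7074900 (SD, n = 6) for libraries labelled WT and 73117095 ± 3549496 (SD, n = 6) for those labelled Q84 (two-sided exact permutation p = 0.182). The labels do not say that each library came from a separate animal, so p-values measure the spread between libraries.

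The sex labels were checked with the Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty, and all 12 libraries matched their label. Ddx3y lay between 127 and 189 CPM in the 4 libraries labelled male and at 0.283 CPM or less in the 8 labelled female. Xist is not listed among the transcripts used here.

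The genotype labels were checked with Atxn3, the mouse counterpart of the transgene, whose transcripts can take up reads of the human gene. One Atxn3 transcript, ENSMUST00000161011.8 of 1000 bases, separated most libraries by label. Its level was 71.4 ± 6.14 TPM (SD, n = 5) in the library labelled Q84 male 1 and those labelled Q84 female 1 to 4. It was 0.110 ± 0.151 TPM (SD, n = 5) in 5 of the 6 libraries labelled WT. The library labelled Q84 female 5 held 0.061 TPM, and the library labelled WT female 2 held 34.0 TPM, which is 47.6% of the mean of the 5 Q84 libraries. These 2 libraries therefore went against their labels in the gene that the genotype is named for, and every direction given below for all 12 libraries includes them under those labels. The longest listed Atxn3 transcript, ENSMUST00000021606.12 of 5363 bases, was at 15.4 ± 0.541 TPM in the same 5 WT libraries and 14.9 ± 1.33 TPM in the same 5 Q84 libraries (SD, n = 5 each).

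Summed over its transcripts, Atxn3 (ENSMUSG00000021189) had a log2 fold change of 0.56 (SE 0.19) between libraries labelled Q84 and WT, and it did not pass the test (edgeR, adjusted p = 0.195, 12 libraries). Without the library labelled Q84 female 5 alone it was 0.68 (adjusted p = 0.00126). Without both doubted libraries, a fit added after the data were seen, it was 0.78 (SE 0.083, edgeR, adjusted p = 0.000183), and 2.46 with length-scaled TPM. These 2 libraries were left out for their Atxn3 levels, so this p-value is no independent test of Atxn3. The neighbouring genes Cpsf2, which encodes an mRNA 3' end processing factor, and Trip11, which encodes a Golgi protein, rose with Atxn3 in the 10 libraries left. Cpsf2 went from 103 ± 6.46 to 186 ± 6.67 CPM and Trip11 from 44.4 ± 5.31 to 74.4 ± 5.62 CPM (SD, n = 5 each). With length-scaled TPM the log2 fold change of Trip11 was 1.52. Whether the added reads came from the mouse genes or from human sequence cannot be told from these counts. Of the 8 tested genes on the list of ATXN3 neighbours, 3 rose, 1 fell (Tc2n, log2 fold change -0.71, a call lost without WT male 2, WT female 1, WT female 3 or Q84 male 1) and 4 did not pass; adjusted over the list alone, 3 rose and 2 fell. The list was called (camera, adjusted p = 0.0356), and the adjusted p = 0.400 with an estimated correlation. It holds Atxn3 itself, so its call is not independent of the choice of libraries either.

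**Figure D1:**
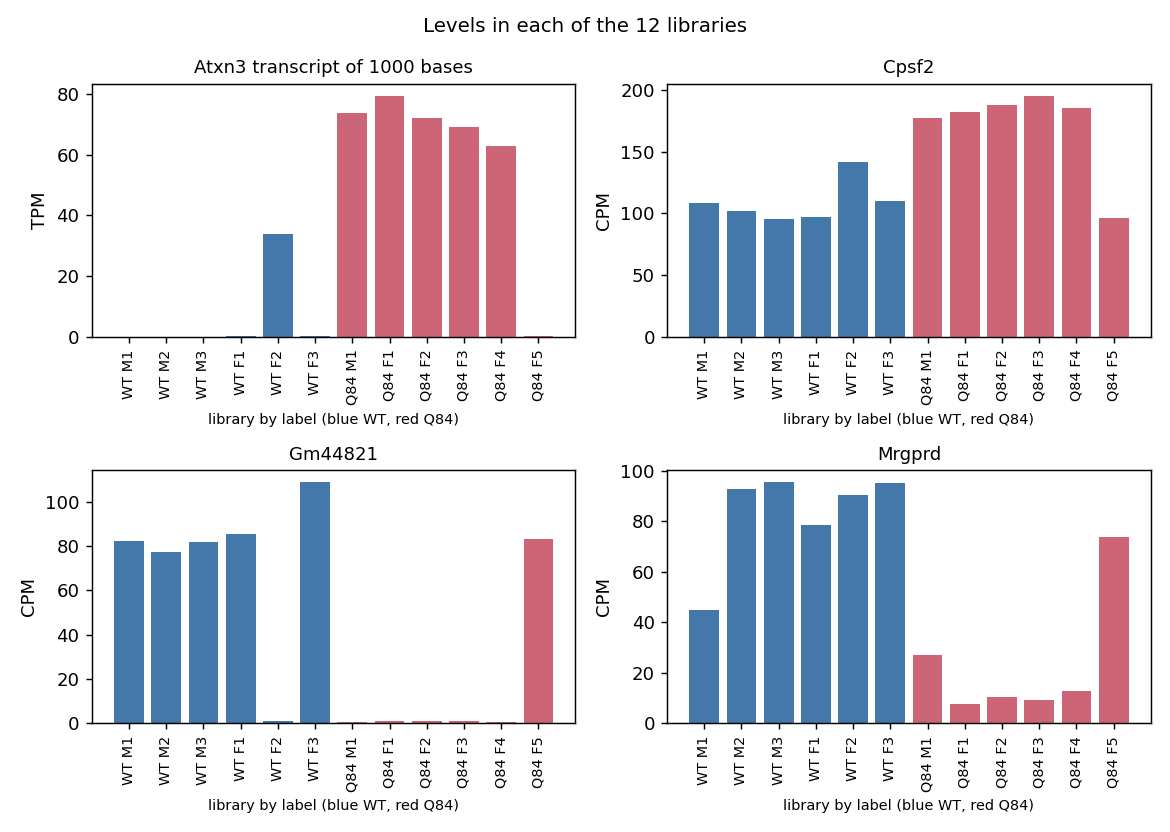
Bars give 1 library each, in TPM for the Atxn3 transcript and in CPM for Cpsf2, Gm44821 and Mrgprd, with WT labels in blue and Q84 labels in red. The library labelled Q84 female 5 sat at 96.2 CPM for Cpsf2 and 73.5 CPM for Mrgprd, and the library labelled WT female 2 at 142 CPM for Cpsf2, 1.27 CPM for Gm44821 and 90.2 CPM for Mrgprd.

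With all 12 libraries as labelled, the comparison of Q84 with WT called 1 gene among 18875 tested (edgeR, 2695 genes at an unadjusted p under 0.05). Chrna7, which encodes the alpha7 subunit of the nicotinic acetylcholine receptor, fell from 77.4 ± 12.8 to 35.7 ± 3.84 CPM (SD, n = 6 each), a log2 fold change of -1.11 (SE 0.13, adjusted p = 0.0143). It was lower in 6 of 6 Q84-labelled libraries, including Q84 female 5 at 37.1 CPM, while the library labelled WT female 2 held 52.8 CPM. Its call was lost without the library labelled WT female 3 (adjusted p = 0.0638), Q84 male 1 (0.200), Q84 female 2 (0.0727), Q84 female 3 (0.0828) or Q84 female 4 (0.0776), with log2 fold changes from -1.11 to -1.02. In the 10 libraries described further on it was -1.27 (edgeR, adjusted p = 1.2e-05). The next genes did not pass: A4galt (-0.65), Slc25a30 (-0.55), Chp2 (-0.52), Gcnt4 (-1.34) and Kctd16 (-0.65) on the lower side, and Cped1 (0.65), Marcks (0.73), Bicc1 (0.54), Ugt2b1, Akr1c6 and Ugt2b35 on the higher side. The last 3 are genes with mean levels of 0.0844 CPM or less. DESeq2 called 620 genes in the same libraries, and limma-voom 1.

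The sensory neuron lists leaned lower in the same 12 libraries, although no member passed over all genes tested. The non-peptidergic nociceptor and itch neuron list, markers of the small unmyelinated neurons that sense pain and itch, had a median log2 fold change of -0.68 over 18 genes. Adjusted over the list alone, 11 members fell, among them Lpar5 (-1.41) and Trpa1 (-0.61). The list was called (camera, adjusted p = 1.96e-11), and the adjusted p = 0.405 with an estimated correlation. The peptidergic nociceptor list had a median of -0.46 over 12 genes, with 6 lower when adjusted over the list alone, among them Calca (-0.72) and Tac1 (-0.44). It too was called (camera, adjusted p = 4.25e-05), and the adjusted p = 0.405 with an estimated correlation. In total 12 of 33 lists were called with the preset correlation, 6 higher and 6 lower, and 0 with an estimated correlation, where 3 lists had an unadjusted p under 0.05. With fry 1 list was called.

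Lists of other cell types were called on the higher side in the 12 libraries. Adjusted over the list alone, all 7 red blood cell genes, 5 of 14 fibroblast genes and 2 of 9 adipocyte genes rose, while no member passed over all genes. Their medians were 1.15, 0.29 and 1.36 on the log2 scale, and each had an adjusted p = 0.405, 0.405 and 0.522 with an estimated correlation. The 13 mitochondrially encoded genes had a median of 0.38, with 11 higher when adjusted over the list alone (adjusted p = 0.405 with an estimated correlation). Their share of all counts was 7.89 ± 0.945% in libraries labelled WT and 10.2 ± 1.15% in those labelled Q84 (SD, n = 6 each, two-sided exact permutation p = 0.00649). The highest share, 11.9%, was in the library labelled Q84 female 5. Also called, each with 0 members past the threshold, were the large-diameter myelinated neuron (median -0.21, 4 lower when adjusted over the list alone), C-fibre low-threshold mechanoreceptor (-0.42), unfolded protein and integrated stress response (-0.12, 2 lower, Atf4 and Ddit3), autophagy and lysosome (-0.09), granulocyte (1.02) and macrophage (0.13) lists. Their adjusted p-values with an estimated correlation were 0.405, 0.602, 0.399, 0.405, 0.602 and 0.702 in that order.

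Leaving out the 2 libraries that went against their labels gave another count. This fit of 10 libraries was added after the data were seen. It called 1208 genes among 18721, of which 285 rose and 923 fell (edgeR). The count rested on the library labelled Q84 female 5. Leaving it out together with any of the 6 WT-labelled libraries gave 590 to 1885 calls, and the other 30 pairs of libraries left out gave at most 3. Leaving out Q84 female 5 alone gave 1082 calls and WT female 2 alone 51. Within the 10 libraries, the count was 1980 without WT male 1, 739 without WT female 3 and 681 without Q84 male 1.

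**Figure D2:**
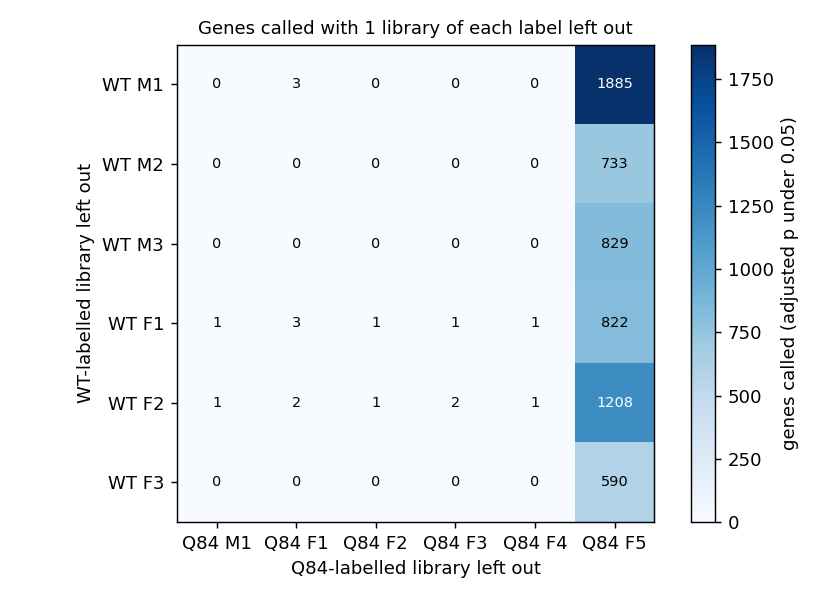
Each cell gives the number of genes called (edgeR, adjusted p under 0.05) when the WT-labelled library of its row and the Q84-labelled library of its column were left out. The 6 pairs that held the library labelled Q84 female 5 gave 590 to 1885 calls and the 30 others at most 3.

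In these 10 libraries 4 genes were nearly silent in Q84, all of them on chromosome 7. Gm44821 went from 87.1 ± 12.4 to 0.919 ± 0.268 CPM, Mrgprx3-ps from 42.8 ± 5.71 to 0.225 ± 0.0948 CPM, and Mrgprb5, of the Mas-related receptors of itch and pain neurons, from 15.0 ± 3.56 to 0.150 ± 0.0489 CPM (SD, n = 5 each). Nps, which encodes neuropeptide S, went from 5.49 ± 0.781 to 0.0187 ± 0.0219 CPM. Their adjusted p-values were 6.8e-10, 8.4e-09, 4.0e-08 and 7.3e-07 (edgeR). Mrgprx3-ps and Mrgprb5 belong to a family of near-identical copies, so how reads were divided among them is uncertain. The library labelled WT female 2 held 1.27, 8.48, 0.379 and 0.0406 CPM of these 4 genes in that order, and the library labelled Q84 female 5 held 83.3, 45.6, 15.8 and 5.73 CPM. Gm5581 (-4.50) and Bmp15 (-4.24) also fell. The rule for named genes further took Krt15, Krt14, Krt13, Gabrp, Slc6a14 and Serpinb3a. Krt15 and Krt14 are keratins of surface epithelium and stood at 80.3 and 16.7 CPM in the library labelled WT female 1 against at most 0.122 CPM in the 11 others. Without that library Krt13 (adjusted p = 0.449) and Serpinb3a (adjusted p = 0.318) did not pass, and the other 4 were too low to be tested. With each of the 10 libraries left out in turn, the calls of Krt13, Serpinb3a, Gabrp, Slc6a14, Krt15 and Krt14 were lost in 8, 7, 7, 7, 6 and 4 fits. These counts cover only fits in which the gene was tested. For Gabrp, Slc6a14, Krt15 and Krt14 the fit without WT female 1 is not among them.

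The largest rises in the 10 libraries included Sema3a, a secreted axon guidance factor (log2 fold change 2.22), Nell1 (2.21), Grxcr2 (1.74), Olfm3 (1.41) and Gprasp2, which encodes a sorting protein of G protein-coupled receptors (1.14). Nell1 went from 4.49 ± 0.213 to 20.4 ± 2.69 CPM and Gprasp2 from 99.0 ± 6.32 to 217 ± 6.59 CPM (SD, n = 5 each; edgeR, adjusted p = 7.3e-07 and 1.9e-06). Vwde, Ccn1, Pcdh11x, Ptpro, Mstn, Nudt17 and Gpr174 rose by 1.13 to 1.33 on the log2 scale. With each of the 10 libraries left out in turn, the call of Ccn1 was lost in 7 fits, that of Mstn without WT female 3 or Q84 male 1, that of Vwde without Q84 male 1 and that of Gpr174 without WT female 3. Vip, which encodes the vasoactive intestinal peptide, rose by 5.13 on the log2 scale (SE 0.31, edgeR, adjusted p = 2.4e-06). Its mean was only 1.225 CPM over the 6 female libraries of these 10, so the WT level behind this fold was close to the floor.

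Many nociceptor genes fell in the 10 libraries. On the non-peptidergic list 13 of 18 genes fell and 5 did not pass (16 fell when adjusted over the list alone), with a median log2 fold change of -1.04. Mrgprd, a receptor of skin-innervating nociceptors, fell from 81.3 ± 21.5 to 13.5 ± 7.91 CPM, and P2rx3, an ATP-gated channel, from 292 ± 61.9 to 130 ± 21.9 CPM (SD, n = 5 each). The library labelled WT female 2 held 90.2 CPM of Mrgprd and the library labelled Q84 female 5 held 73.5 CPM. On the peptidergic list 5 of 12 fell and 7 did not pass (8 fell and 1 rose when adjusted over the list alone), with Calca from 1812 ± 166 to 1025 ± 180 CPM and Calcb from 223 ± 42.2 to 113 ± 17.3 CPM, both encoding calcitonin gene-related peptides. Both lists were called (camera, adjusted p = 1.47e-14 and 0.000161), and for both the adjusted p = 0.400 with an estimated correlation. On the list of large-diameter myelinated neurons 5 of 18 fell, among them Calb1 (-0.82) and Nefl (-0.50), and 8 fell when adjusted over the list alone. On the C-fibre low-threshold mechanoreceptor list 2 of 7 fell, P2ry1 (-1.07) and Slc17a8 (-1.51), and 6 when adjusted over the list alone. With each of the 10 libraries left out in turn, the call of Nefl was lost in 8 fits and that of Slc17a8 in 7, with Slc17a8 at -0.92 without WT female 3, and those of Calb1 and P2ry1 in 0. Both were called (camera, adjusted p = 1.92e-05 and 0.00038), with adjusted p = 0.400 and 0.430 with an estimated correlation. The mitochondrially encoded share of counts was higher by 1.83 percentage points in the same Q84 libraries (two-sided exact permutation p = 0.0238, n = 5 each).

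**Figure D3:**
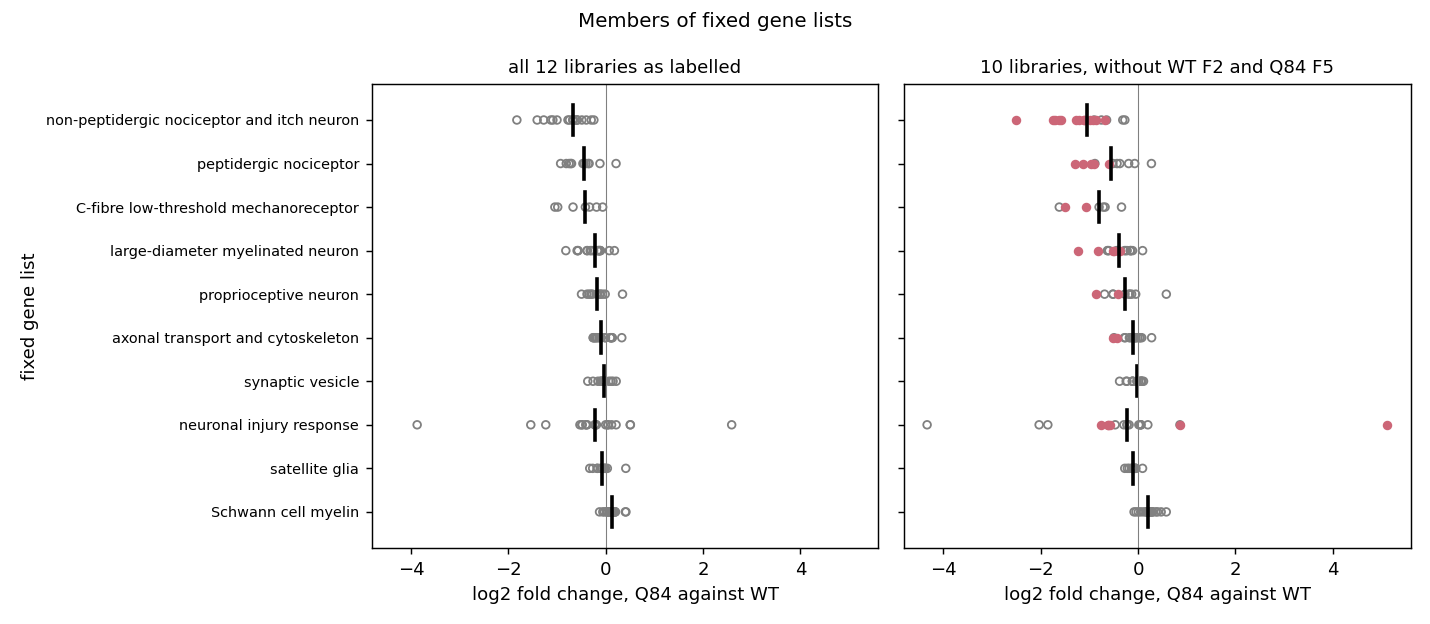
Points give the log2 fold change of each member of 10 fixed lists, filled where the adjusted p was under 0.05, and black bars give the list's median, for the 12 libraries as labelled and for the 10 libraries. The non-peptidergic median was -0.68 in the 12 and -1.04 in the 10 libraries, and the synaptic vesicle median was -0.05 and -0.02.

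Other lists were as follows in the 10 libraries. On the synaptic vesicle list, genes that all neurons use, 0 of 14 genes passed and the median was -0.02. On the neuronal injury response list 2 of 20 rose, Vip and Lmo7, and 4 fell, Adcyap1, Atf3, Nts and Jun (3 rose and 9 fell when adjusted over the list alone). Atf3, a transcription factor that nerve damage induces, was at 5.94 ± 1.23 CPM in WT and 3.38 ± 0.420 CPM in Q84 (SD, n = 5 each). The list was not called (camera, adjusted p = 0.162). On the Schwann cell myelin list 0 of 20 passed, although the list was called (camera, adjusted p = 0.0356, median 0.21), and the adjusted p = 0.757 with an estimated correlation. On the mitochondrially encoded list 1 of 13 rose, mt-Nd2 (0.56), 5 rose when adjusted over the list alone, and the list was called (camera, adjusted p = 0.00038), with an adjusted p = 0.529 with an estimated correlation. On the red blood cell list 0 of 7 passed (7 rose when adjusted over the list alone, median 1.27), and on the granulocyte list 0 of 10 passed (1 rose, median 1.12), with an adjusted p = 0.529 for both with an estimated correlation. On the fibroblast list 1 of 14 rose, Pdgfra (3 when adjusted over the list alone), on the adipocyte list 0 of 9 (1 rose, median 1.54), and on the proprioceptive neuron list 2 of 11 fell, Kcnc1 (-0.85) and Fam19a1 (-0.41). These 3 lists were called, with adjusted p = 0.578, 0.578 and 0.529 with an estimated correlation. In total 14 of 33 lists were called with the preset correlation, 0 with an estimated one and 7 with fry. With each of the 10 libraries left out in turn, the calls of Jun and Kcnc1 were lost in 7 fits each, that of Atf3 in 5 (log2 fold changes from -0.95 to -0.56 over the 10 fits) and that of Nts in 4. Those of Adcyap1, Fam19a1 and mt-Nd2 were lost without WT female 3 or Q84 male 1, and that of Pdgfra without Q84 male 1.

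In the 8 female libraries as labelled, 3 WT and 5 Q84, 0 genes were called among 17244 tested (edgeR). At an unadjusted p under 0.05 there were 1826, DESeq2 called 149 and limma-voom 0. The genes of smallest p were mt-Nd3 (0.67), Grip2 (0.42), mt-Nd1 (0.55), Egr1 (1.34), Rpl22l1 (0.50) and Srd5a2 (1.96) on the higher side and Chrna7 (-1.03), Cds2 (-0.51), Kcnip2 (-1.25), F2rl1 (-1.19), Trpm8 (-0.83) and Lgmn (-0.46) on the lower side, with adjusted p from 0.274 to 0.339, and none passed. Without the 2 doubted libraries, a fit of 2 WT and 4 Q84 libraries added after the data were seen, 891 genes were called, 229 higher and 662 lower. Leaving out only the library labelled Q84 female 5 gave 843 calls and only WT female 2 gave 3. Of the calls in these 6 libraries, 682 were among the 1208 of the 10 libraries. Rises in these 6 libraries included Htr2c (1.76), Tnmd (1.52) and Hoxc10 (1.42), and falls Hal (-3.59), Adtrp (-3.44), Wnt2b (-3.26), Ighg2c (-3.07) and Slc51a (-3.64). On the non-peptidergic list 14 of 18 fell (16 when adjusted over the list alone), and the adjusted p = 0.584 with an estimated correlation. In the 8 female libraries as labelled that list had a median of -0.70, with 2 lower when adjusted over the list alone, P2rx3 and Lpar5, and the mitochondrially encoded list one of 0.51, with 10 higher. Of 33 lists 11 were called there, and 0 with an estimated correlation, where both lists had an adjusted p = 0.662. With fry 0 lists were called there and 2 in the 6 female libraries.

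Between the sexes 12 genes were called (edgeR, 18875 tested). Uty, Ddx3y, Eif2s3y, Kdm5d and Uba1y, all Y-linked, were higher in males, as were Akr1c6, Acsm2, Ugt2b35 and Ugt2b1. The means of Akr1c6, Ugt2b35 and Ugt2b1 over the 12 libraries were only 0.0844, 0.0402 and 0.0534 CPM, close to the floor. Gm26992, Eif2s3x and Kdm6a were lower in males, with log2 values of -0.74 and -0.57 for the last 2. Akr1c6 stood at 0.917 CPM in the library labelled Q84 male 1 and at 0.0354 CPM or less in the 11 others. Without the library labelled Q84 male 1 the count was 6, and without WT female 1 it was 23.

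The genotype difference differed between the sexes for 8 genes (edgeR interaction term), all with larger values in the Q84 male. They were Apoa2, Alb, Ahsg, Serpina3k, Serpina1c, Cyp2e1, Gm16867 and Ttr, and the 7 of these other than Gm16867 are genes that liver expresses strongly. Alb stood at 19.5 CPM in the library labelled Q84 male 1 and at 0.975 CPM or less in the other 11. The lower values of smallest p, Gm10131 (adjusted p = 0.219), Gm14405 and Gm14308 (both 0.531), did not pass. The 1 Q84 male was taken to vary like the other groups, so the interaction has no replicate of that group. Acta1, an actin of skeletal muscle, also varied between libraries of one label, from 0.657 to 219 CPM in those labelled Q84 and from 0.791 to 98.2 CPM in those labelled WT.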

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

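All tests of explanations in this part except the counts over pairs of libraries, over splits of the libraries and over the Mrgpr family were chosen after the results were seen. Of the excepted counts, those on the pair left out, on the 10 libraries and on the Mrgpr family concern patterns that had been seen in the data first. Among the tests chosen after the results, the SD around the midpoint in the tests of wrong labels was added after the library labelled WT female 2 came out at 50.2%. The test of mixed RNA replaced a first version that did not decide. It is given with each of 2 readings of its SD and without its minimum level. With 29 results checked for a library far from the others, chance alone flags about 1 in 20.

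The library labelled Q84 female 5 lay far below the other 4 Q84 females in Atxn3 (gap over range 0.748), Cpsf2 (0.901) and the 1000-base Atxn3 transcript (0.790), and the library labelled WT female 2 held 34.0 TPM of that transcript. Over 970 genes of 1 CPM or more that were called in the 10 libraries and lie outside the ATXN3 neighbours, the library labelled Q84 female 5 lay 2.38% of the way from the WT to the Q84 mean. A wrong label on it therefore remains a candidate explanation. Its Chrna7 level matched the other Q84 libraries, and its mitochondrially encoded share of counts was the highest (11.9%). Chrna7 was the 1 gene called with this library under its Q84 label, however. That match was therefore selected for and does not count against a wrong label. Of the 970 genes, 20.2% lay nearer the Q84 than the WT mean in this library. Of the genes at the locus, Trip11 lay 42.1% of the way in it, but Atxn3 lay at -26.2% and Cpsf2 at -7.83%. The library labelled WT female 2 lay 50.2% of the way by the mean and 42.6% by the median. The library labelled WT male 1, placed by a fit without it over 1715 genes, lay 27.7% of the way by the mean and 43.2% by the median. The mean of WT female 2 lies inside the 13.8 percentage point SD of the other WT libraries around the midpoint. This position therefore does not decide whether its label is wrong. A lower transgene dose, which could also place a library near the midpoint, was not tested. Of the genes at the locus, Atxn3 lay 43.8%, Cpsf2 47.5% and Trip11 54.7% of the way in the library labelled WT female 2. Its 34.0 TPM of the 1000-base Atxn3 transcript, against at most 0.285 TPM in the other 5 WT-labelled libraries, sets it apart from those libraries. RNA of a Q84 animal mixed into WT female 2 is not excluded by the bound set for it. Of the 16 strongly lowered genes of 10 CPM or more, 2 (Gm44821 and Lair1) lay more than 3 SD of the WT libraries below the 52.4% of the WT level that such mixing would leave, short of the 3 genes set for this test. With the SD scaled to that share, 4 did, Mrgprb5 and Mrgprx3-ps being added. Of the 16, 8 lay above that level, with Mrgprd at 110.9% of its WT level. Without the minimum of 10 CPM, counted after that result, 6 of all 47 strongly lowered genes lay more than 3 SD of the WT libraries below that level, Nps (3.63 SD) among them, which goes against such mixing. A first version of this test, the share of all 47 strongly lowered genes under that level, was 68.1% and did not decide. Of the 36 pairs of 1 WT and 1 Q84 library left out, 2, this pair with 1208 included, gave as many calls, and the highest other was 1885 with WT male 1 in place of WT female 2, so the count does not single out this pair.

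For nociceptor genes in the 10 libraries, a lower share of neurons is argued against, since the synaptic vesicle median lay 1.02 above the non-peptidergic median on the log2 scale (permutation p = 3e-04 over genes, which are not independent). Unequal numbers of males and females are argued against by a non-peptidergic median of -1.11 in the 6 female libraries. Ganglia from other spinal levels stay open: Hox 9 to 11 genes lay 0.31 above Hox 4 to 6 genes (permutation p = 0.011), just past the bound set for that test, with 0 of the 10 genes in each group called. The genotype, and a change in the makeup of neuron types, stay among the open explanations, as untested.

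For the nearly silent Mrgpr genes and Nps, reads shifted between near-identical copies are argued against, since the summed level of 34 Mrgpr genes, with Gm44821 counted among them, differed by -1.91 on the log2 scale between Q84 and WT (two-sided exact permutation p = 0.00794, n = 5 each). A chromosome segment of another strain carried with the transgene stays open: 132 neighbouring pairs of called genes were found against at most 113 in 10000 random draws of as many genes (permutation p = 1e-04, the smallest they can give), a count that neighbouring genes with shared regulation could give as well. No chromosome was enriched in calls after adjustment (lowest adjusted p = 0.0685, chromosome 3; chromosome 7, unadjusted p = 0.0432, adjusted p = 0.562). Of the 47 strongly lowered genes 10 lie on chromosome 7, the most of any chromosome, which was not tested.

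The interaction term of genotype and sex passed for Apoa2 (3.62 on the log2 scale), Ahsg (7.40), Cyp2e1 (3.47), Alb (4.76), Serpina3k (4.66), Ttr (2.72), Serpina1c (5.14) and Gm16867 (8.50). These values rest on the 1 library labelled Q84 male, which held 19.5 CPM of Alb against 0.975 CPM or less in the 11 others, so a difference of this library alone is not separated from one between the sexes. Marcks in the library labelled Q84 female 1 stood apart from the other Q84 females (gap over range 0.725).

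Other splits of the libraries bear on each count. For the 12 libraries, 7 of 100 splits gave as many calls as the 1 observed (highest other 89), and 27 of 100 gave as many called lists as the 12 observed (highest other 20), so chance is not excluded. For the females the 0 observed is the lowest count there can be, so that 56 of 56 splits gave as many says nothing about chance. The highest other, 406, differed from the labels only in exchanging the libraries labelled WT female 2 and Q84 female 5, which parts the females with 34.0 TPM or more of the 1000-base Atxn3 transcript from those with less. For sex, 4 of 100 splits, drawn from 495 possible ones, gave 12 or more (highest other 45). This is just under the bound of 0.05, and a draw of this size cannot place it firmly on either side. Chance is therefore not excluded for the number of calls. The 89 calls came from setting the libraries labelled WT male 1, WT female 1 and 2, Q84 male 1 and Q84 female 1 and 5 against the others, and the 45 from setting WT female 1, Q84 male 1 and Q84 female 2 and 3 against the others. These splits follow neither the labels nor that transcript, so they point to further structure among the libraries. Of 33 lists, compared with these splits after they were seen, 2 part the libraries as the split of 89 does: the skeletal muscle list, with a mean log2(CPM + 1) of 3.03 to 6.50 in those 6 libraries and 0.454 to 2.19 in the others, and the meninges and perineurium list (3.20 to 3.62 and 2.74 to 3.09). The macrophage list alone parts them as the split of 45 does (3.58 to 4.00 and 3.01 to 3.39). Over so many lists such a match can arise by chance, which was not tested. For the 10 libraries 1 of 100 splits, the real one, gave 1208 calls (highest other 196). The splits were drawn from 126 possible ones. A chance division of these 10 is therefore unlikely for the number of genes. It is not excluded, since 100 splits can give no smaller share and the 10 libraries were chosen after the data were seen. Of the 100 splits, 15 gave as many called lists as the 14 observed (highest other 19). For the number of lists chance is not excluded either.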

How the results depend on the processing

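The alternatives on 10 libraries, and leaving out the libraries labelled WT female 2 and Q84 female 5 together, were chosen after seeing the data. The cause of the differences was not tested beyond the libraries named. For Q84 against WT the 1 call became 620 with DESeq2, 15 with no filter, 193 with no sex covariate, 1334 with voom quality weights and 1208 without both doubted libraries, and 0 to 1082 with each library left out. In females the 0 calls became 149 with DESeq2 and 891 without both, and 0 to 843 with each library left out. For the interaction the 8 calls became 31 with DESeq2, 16 with limma-voom and 5 with a mean CPM of 1 or more, and 6 to 10 with each library left out; it could not be fitted without the Q84 male. For sex the 12 calls became 21 with DESeq2 and 7 with a mean CPM of 1 or more, and 6 to 23 with each left out. The called lists went from 12, and from 14 in the 10 libraries, to 0 with an estimated correlation; in the 10 libraries females alone gave 9 and libraries left out in turn 9 to 18. The 1208 calls became 1934 with DESeq2, and 681 to 1980 with each left out. Replicate numbers do not pair the libraries: same-numbered females correlated at -0.0075, -0.128 and 0.0904. The replicate block gave 142 calls in the 12 libraries, 475 in females and 158 in the 10 libraries, and an Atxn3 log2 fold change of 0.71 that passed. In that block the libraries labelled WT male 2 and 3 and Q84 female 4 and 5 had no partner of the other label. In the 10 libraries Q84 female 2 had none either, so the 158 calls rest on the pairs male 1, female 1 and female 3. Libraries without a partner added nothing to the genotype estimate of the block. These counts therefore also leave out Q84 female 5 and do not show an effect of pairing alone. Atxn3 was 0.49 to 0.68 with each library left out, 0.78 without both, and 1.76 with length-scaled TPM, where it did not pass (adjusted p = 0.153). In the 10 libraries Atxn3 went from 0.78 to 2.46 and Trip11 from 0.75 to 1.52 with length-scaled TPM, and both passed; Trip11 did not pass with the replicate block (0.71, adjusted p = 0.0664). With limma-voom Krt15, Krt14, Gabrp, Slc6a14 and Krt13 were at -6.23, -6.03, -4.05, -4.79 and -4.55 there, and none of these passed. Of the calls of genes that the rule names in the 10 libraries, 2 to 32 were lost with each library left out, most without Q84 male 1 (32) and WT female 3 (28). With other scaling or length-scaled TPM, the median over genes of the change in log2 fold change was 0.00772 or less in size. No named gene changed direction.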

Other observations

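Smaller groups in the 10 libraries, a fit added after the data were seen, also held named changes. On the list of repair and non-myelinating Schwann cell genes 3 of 13 fell, Ngfr from 55.5 ± 8.88 to 29.6 ± 4.70 CPM, Scn7a (-0.56) and Shh (-0.97), and Bdnf rose from 36.9 ± 2.19 to 57.9 ± 3.72 CPM (SD, n = 5 each; edgeR). Bdnf encodes a neurotrophin that sensory neurons also make. On the endothelium and pericyte list of 12 genes Rgs5, a pericyte gene, fell from 379 ± 75.7 to 148 ± 7.90 CPM, while Abcc9, another pericyte gene, rose by 0.85 on the log2 scale. On the T cell list Cd8a (-1.25) and Cd3e (-1.11) fell. With each of the 10 libraries left out in turn, the call of Cd3e was lost in 5 fits, and those of Cd8a and Abcc9 without WT female 3 or Q84 male 1.

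Stress pathway lists showed few calls. On the proteasome list 1 of 31 fell, Psmc5 (-0.25), and on the heat shock list 1 of 14 rose, Hspa8 (0.31). On the unfolded protein and integrated stress response list 2 of 17 fell, Atf4 (-0.31) and Ddit3 (-0.33), and that list was not called. On the autophagy and lysosome list 1 of 15 fell, Lamp2 (-0.32). On the nuclear-encoded oxidative phosphorylation list 0 of 28 passed and on the cholesterol synthesis list 0 of 21. On the axonal transport and cytoskeleton list 2 of 17 fell, Kif5b (-0.44) and Kif5c (-0.51). With each of the 10 libraries left out in turn, the calls of Psmc5 and Hspa8 were lost in 9 fits each, that of Lamp2 in 8, Ddit3 in 7, Kif5c in 4, Atf4 in 2 (without WT female 3 or Q84 male 1) and Kif5b in 1 (without WT female 3). The T cell and heat shock lists were called (camera, adjusted p = 0.0356 each), with an adjusted p = 0.578 and 0.430 with an estimated correlation. On the central nervous system list 1 of 12 rose, Gad1 (0.71), and 1 fell, Aqp4 (-0.72), on the cartilage and bone list 1 of 7 fell, Ibsp (-0.73), on the meninges and perineurium list 1 of 7 rose, Cldn1 (0.71), and on the immediate early list 1 of 10 fell, Arc (-1.53). These lists were not called. In the same fits the call of Gad1 was lost in 7, that of Ibsp in 3 (without WT female 1, WT female 3 or Q84 male 1), that of Arc in 2 (without WT female 1 or Q84 male 1), that of Aqp4 in 1 (without WT female 3) and that of Cldn1 in 0. The satellite glia, macrophage, interferon response, skeletal muscle and circadian clock lists had 0 members past the threshold and were not called.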
